A study of Mus musculus with 8 samples.

How the data were processed

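Total RNA from liver sinusoidal endothelial cells of C57BL/6N mice aged 8 weeks was profiled on Illumina bead arrays, microarrays on which each probe is carried on a set of beads. Cells were isolated 1 day after a sham operation (4 samples) or after removal of 2/3 of the liver (4 samples) and were lysed without culture, per the labels' protocols. Biotinylated cRNA was prepared with a linear amplification kit made for this type of array, per the labels' protocols. The labels give a number from 1 to 4 to each sample of a group. They do not say that the samples came from separate mice or whether cells of several mice were pooled, so the p-values measure the spread between these samples, which may be partly technical.

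The deposited table holds 1 value for each of 25622 probes on each of the 8 arrays, with no missing value. The values are linear intensity values, as deposited by the authors, and run from 81.0 to 26223 across the arrays. The array design, scanner software, normalization, background treatment and any filter on probes are not given in the sources used here. From the values themselves, the arrays had already been brought to nearly the same distribution: median intensity ranged from 119.9 to 120.7, and no array's median log2 intensity was off the mean of the medians by more than 0.0056. The lowest values stayed near 80, so the values hold an intensity floor, which may be background that was not removed. Such a floor makes fold changes of dim probes smaller than the underlying change. The table has no detection p-value and no bead number, so no probe was called detected or not detected, and precision was judged only from the spread between arrays. No 2 arrays held identical values.

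The table does not pair its probe identifiers with genes, and the gene table used here holds no identifiers of this kind (0 probes matched). Results are therefore given per probe. The 24 lists of genes fixed before the data were examined (428 entries, 410 different genes, covering endothelial identity, growth factors, cell cycle, inflammation and markers of other liver cells) and the genes to be reported in every case were not analysed here. The choice of 1 probe per gene, and the alternative of averaging a gene's probes, did not apply, and every probe was tested on its own.

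Intensities were taken to log2 with no pseudocount and no filter. The authors' normalization was kept, because the rule set before the data were examined called for quantile normalization only if a median was off by more than 0.1 on the log2 scale. Hepatectomy was compared with sham in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend in the prior variance, on all 8 arrays and without covariates. P-values were adjusted by the Benjamini-Hochberg method over the 25622 probes and called at 0.05. Counts at a change of at least 2-fold (1 on the log2 scale) are given as well. The rule for named probes asked for the largest rises and falls among called probes whose groups did not overlap and whose mean in the higher group was above the median of all probes. Because no gene names are used, 2 probes each way are named. The same fit was tested on simulated data made from the means and spreads of the 25622 probes. In these data 200 probes, all drawn from those brighter than the median, were changed. The fit recovered 70.1% of simulated changes of 0.5 on the log2 scale, 95.5% of changes of 1 and all 66 changes of 2, with 7 false calls. The simulation had independent noise, no intensity floor and far fewer changed probes than were called here. Its rates check the fit and do not carry over to the real data, least of all to dim probes.

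The position of each array between the group means was computed after the data were seen. For each array the fit was repeated without it, the probes called with a change of at least 2-fold were taken, and the array's log2 value was placed on a scale on which 0 is the mean of the remaining sham arrays and 1 the mean of the remaining hepatectomy arrays. Arrays were also compared by Spearman correlation over all probes and by principal components of the log2 values. Samples with the same number in the sham and hepatectomy groups did not deviate together. The correlations of their deviations from the group means, over the probes brighter than the median, were 0.021, -0.077, -0.065 and 0.030 for numbers 1 to 4. The main fit had no block for the number, a choice made before the data were examined. The reason was that the labels do not say that a number marks a shared day or litter.

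Alternatives set before the data were examined were quantile normalization, median centring, cyclic loess, the replicate number as a block, eBayes without the trend, array weights, a filter to probes brighter than the median, an offset of 16 before log2, and leaving out each array in turn. A normexp background correction with an offset of 16 was added after the data were seen.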

Results

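Gene expression was measured in liver sinusoidal endothelial cells, the fenestrated cells that line the liver's capillaries, taken from mice 1 day after a sham operation or after partial hepatectomy, in which 2/3 of the liver was removed. The design asked how the expression profile of these cells differs between the resting and the regenerating liver. Each group held 4 arrays, and each array gave an intensity for 25622 probes. Total intensity per array lay between 12164500 and 12289600, so the arrays were closely matched in overall signal. The probes are given here by their identifiers, without gene names.

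The hepatectomy and sham arrays formed separate groups. The first principal component carried 71.1% of the variance of the log2 intensities. On it the sham arrays scored from -35.9 to -16.5 and the hepatectomy arrays from 22.8 to 31.5. Spearman correlations over all probes were 0.905 to 0.916 between sham arrays, 0.913 to 0.918 between hepatectomy arrays and 0.889 to 0.902 between arrays of different groups. Within the sham group, replicate 4 stood apart. It had the score nearest to the hepatectomy arrays on the first component, and it scored -25.4 on the second component, which carried 9.09% of the variance, against 4.84 to 8.37 for sham replicates 1 to 3.

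**Figure D1:**
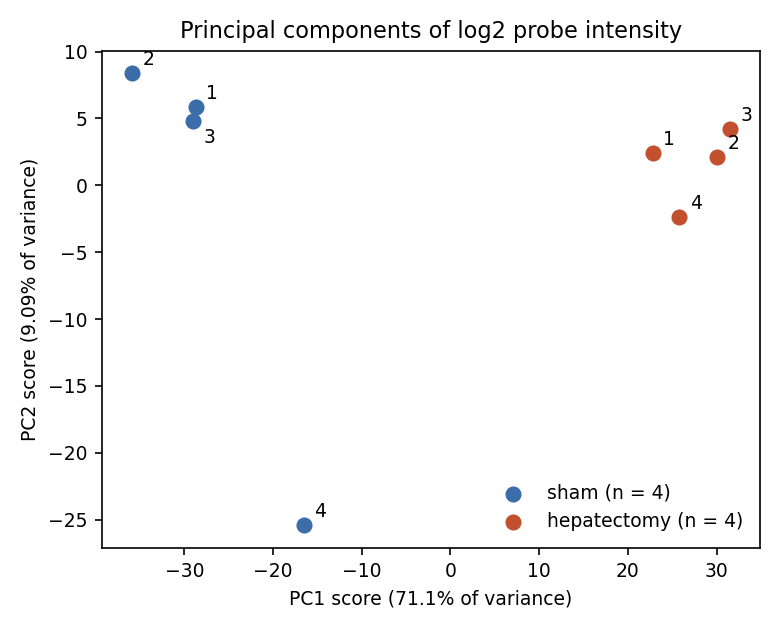
Scores of the 8 arrays on the first (x axis) and second (y axis) principal component of log2 probe intensity, in log2 units, with each point numbered by replicate. Sham arrays (blue) lie at or below -16.5 on the first component and hepatectomy arrays (red) at or above 22.8, while sham replicate 4 lies at -25.4 on the second.

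The signal of 4423 of 25622 probes (17.3%) differed between hepatectomy and sham at an adjusted p under 0.05 in limma. Of these, 2047 rose and 2376 fell. Whether the mix of cells differed between the groups was not tested, because that needs gene names. The differences may therefore not all lie within the endothelial cells. The median change was 0.52 on the log2 scale among probes that rose and -0.43 among probes that fell, with a median standard error of 0.097 over the called probes. Most changes were small, with 3837 called probes changing by less than 2-fold, of which 1618 rose and 2219 fell. The order of the counts depended on the scaling between arrays: after cyclic loess normalization 2379 probes rose and 1910 fell. At an unadjusted p under 0.05, 6934 probes differed, against 1281 expected by chance. The hepatectomy and sham values did not overlap at all for 5201 probes (20.3%), where chance gives 2.86% for 4 arrays against 4, and 3958 of the 4423 called probes were among them. The calls rest on the same arrays, so the last count is not separate support for them. Without sham replicate 4, the array that stood apart, 2285 probes rose and 2837 fell.

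Larger changes were mostly increases. In limma, 429 probes rose at least 2-fold and 157 fell at least 2-fold, so 73.2% of these 586 probes rose. At 4-fold or more, 106 probes rose and 16 fell. At 8-fold or more, 25 rose and 2 fell, and 6 probes rose at least 16-fold. Of the probes with a change of at least 2-fold, 421 of the 429 that rose and 153 of the 157 that fell had no overlap between the 4 sham and 4 hepatectomy values. They were called on these same arrays, so this separation largely follows from the choice and is no separate support. The median standard error was 0.16 on the log2 scale for those that rose and 0.12 for those that fell. Only 6 further probes changed by at least 2-fold without passing the threshold. Without sham replicate 4 the counts were 477 up and 181 down. The counts depended on how the intensity floor was treated, and after the normexp correction 704 probes rose and 338 fell at least 2-fold. Probes near the floor have no room to fall 2-fold, which can favour rises in these counts. Which direction led also depended on the probes taken. Among the 10% of probes brightest in sham, 56 rose and 87 fell at least 2-fold. Among the 10% brightest after hepatectomy, 196 rose and 30 fell, and each choice favours probes brighter in its group.

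The probes that rose at least 2-fold had lower signals in sham cells than those that fell. The median of their mean intensities (geometric means over the arrays of a group) was 231 in sham and 824 after hepatectomy, and 188 of the 429 lay above the 75th percentile of all probes in sham. The probes that fell at least 2-fold started brighter, with a median of 1072 in sham and 369.6 after hepatectomy, and 103 of the 157 still lay above the 75th percentile after hepatectomy. Together the 429 rising probes gave 2.00% ± 0.44 (SD, n = 4) of an array's total intensity in sham and 7.05% ± 0.68 (SD, n = 4) after hepatectomy. The 157 falling probes gave 2.27% ± 0.13 (SD, n = 4) in sham and 0.849% ± 0.073 (SD, n = 4) after hepatectomy. Both sets were chosen on these arrays, so the starting signals and the shares describe the sets and are not a separate test. A probe near the intensity floor can rise but has no room to fall 2-fold. The choice by itself thus favours lower sham signals among the rising probes.

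Calls were spread unevenly over the brightness range. Of the 6406 dimmest probes, with mean intensities up to 105, limma called 0.702%. Of the 2563 brightest, with mean intensities above 916, it called 41.1%, with 434 up and 620 down. No probe with a mean intensity under 119 was called with a change of at least 2-fold. No value lay below 81.0, so probes this dim had almost no room for such a change. The floor also makes smaller changes of dim probes harder to see, so the uneven spread does not show where expression changed. Among the 5406 probes that lay above the 75th percentile on all 8 arrays, 797 rose and 1210 fell.

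**Figure D2:**
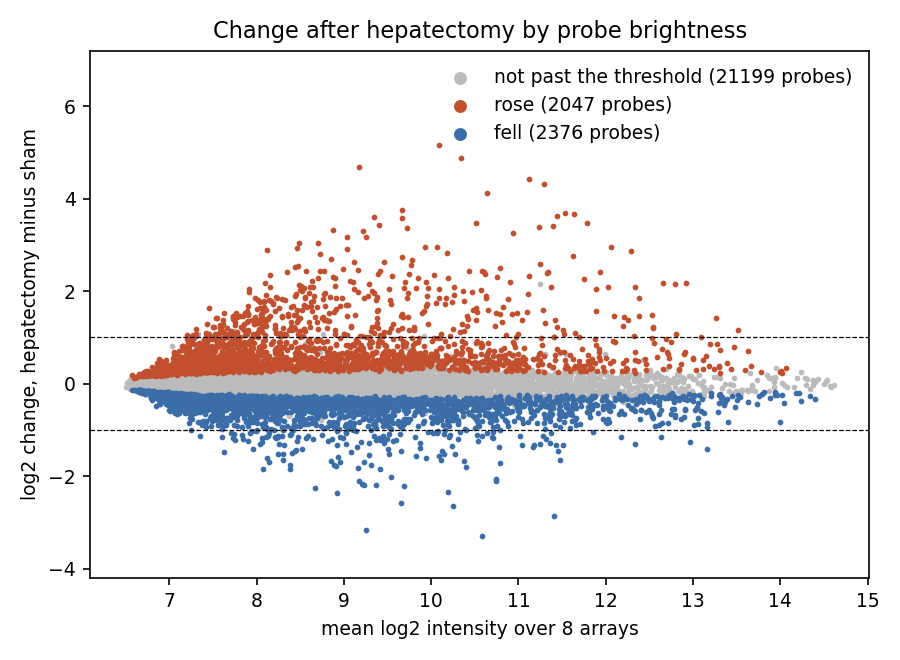
Log2 change of each probe from sham to hepatectomy (y axis) against its mean log2 intensity over the 8 arrays (x axis), with dashed lines at a 2-fold change. The 2047 probes that rose (red) and the 2376 that fell (blue) lie mostly within 2-fold, and the changes beyond 2-fold are mainly increases (429 against 157).

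The largest increase was at probe ILMN_2712075, whose intensity was 240 ± 231 (SD, n = 4) in sham and 6848 ± 2249 (SD, n = 4) after hepatectomy. Its log2 change was 5.16 with a standard error of 0.41 (limma adjusted p = 5.66e-07). Sham replicates 1 to 3 gave 105 to 137 for this probe, close to the array median, while sham replicate 4 gave 586. With the sham values this close to the intensity floor, the size of the change depended on how the floor was treated. The log2 change was 6.16 after a normexp background correction. Probe ILMN_1246800 followed, with 296 ± 247 (SD, n = 4) in sham and 7384 ± 2526 (SD, n = 4) after hepatectomy, a log2 change of 4.88 with a standard error of 0.37 (limma adjusted p = 4.57e-07), or 5.53 after the background correction. Sham replicate 4 was again the highest sham array, at 663 against 129.9 to 197 in the others, and the lowest hepatectomy array was at 4670.

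The largest decreases were at probes ILMN_1215862 and ILMN_2737710. ILMN_1215862 fell from 4885 ± 875 (SD, n = 4) in sham to 503 ± 136 (SD, n = 4) after hepatectomy. This was a 9.86-fold decrease of the geometric means, with a log2 change of -3.30 and a standard error of 0.17 (limma adjusted p = 2.04e-08). Probe ILMN_2737710 fell from 1943 ± 705 (SD, n = 4) to 209.6 ± 56.9 (SD, n = 4), a log2 change of -3.17 with a standard error of 0.23 (limma adjusted p = 3.37e-07), or -3.76 after the background correction. Sham replicate 4 was the highest sham array for ILMN_1215862, at 6116, and the lowest for ILMN_2737710, at 1063. Without it the order of these probes turned, with log2 changes of -3.19 for ILMN_1215862 and -3.43 for ILMN_2737710.

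**Figure D3:**
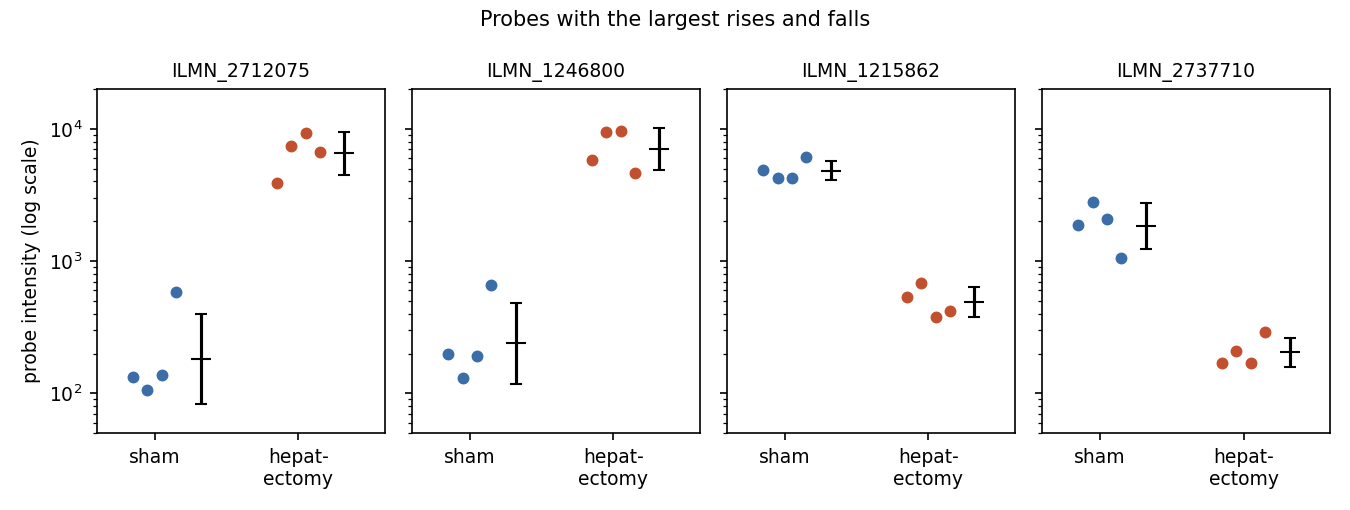
Intensity (y axis, log scale) of the 2 probes that rose most and the 2 that fell most in the 4 sham (blue) and 4 hepatectomy (red) arrays, points in replicate order, with the mean ± SD of the log2 values in black. All 4 hepatectomy values lie outside the sham range for each probe, as the rule for choosing the probes required. Sham replicate 4 is the highest sham array for both rising probes, at 586 and 663.

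The arrays of each group differed in how far they lay along the hepatectomy change. On probes chosen without the array itself, sham replicate 4 lay at a median position of 0.23 (quartiles 0.11 and 0.38, 477 rising probes), where 0 is the mean of the other sham arrays and 1 the mean of the hepatectomy arrays. Sham replicate 2 lay on the other side, at -0.204, and sham replicates 1 and 3 lay at -0.0046 and 0.019. Each array has its own 0 and its own probes, so these positions are not on a single scale. Replicate 4 is part of the 0 for replicate 2, and replicate 2 of that for replicate 4. Each of these positions thus partly reflects the other array. On falling probes the sham arrays lay at 0.049, -0.085, 0.014 and 0.17 for replicates 1 to 4. The hepatectomy arrays lay between 0.85 and 1.10 on rising probes and between 0.90 and 1.09 on falling probes. The median SD within a group, over the probes brighter than the median, was 0.12 on the log2 scale in sham and 0.11 after hepatectomy. It was 0.090 in sham without replicate 4. That value rests on fewer arrays and leaves out the array that stood apart. Both tend to lower an SD, so it cannot be set against the hepatectomy value.

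**Figure D4:**
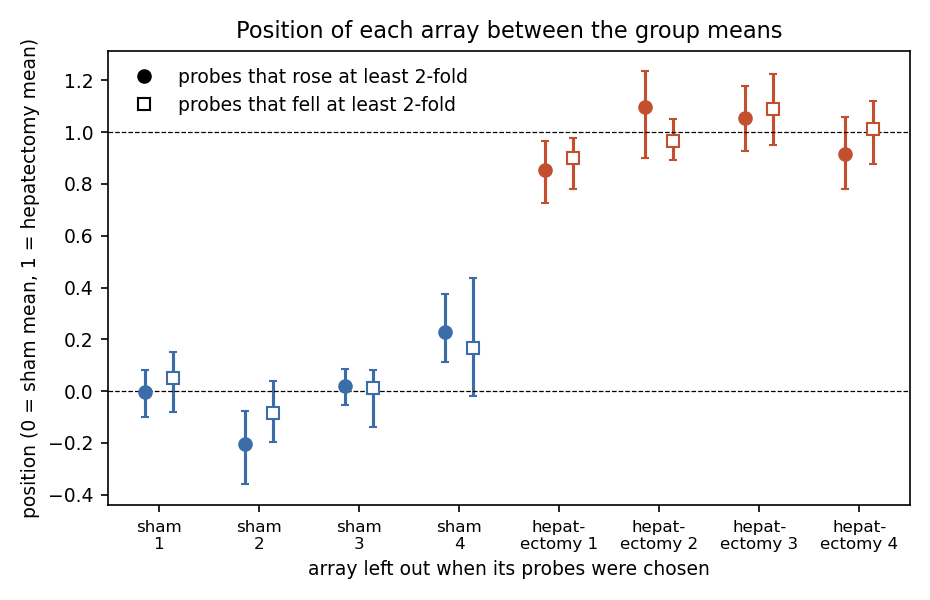
Position of each array (x axis) between the mean of the sham arrays (0) and of the hepatectomy arrays (1) on the log2 scale (y axis), as the median with quartiles over probes that rose (filled circles) or fell (open squares) at least 2-fold in a fit without that array. Sham replicate 4 lies at 0.23 on rising probes, above the other sham arrays, and every hepatectomy array lies at 0.85 or higher.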

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

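The tests of sham replicate 4, of other splits and of brightness in a single group were chosen after the results were seen, as was the use of cyclic loess, a normalization set before the data were examined, as a test of the excess of 2-fold rises; the other tests of the excess of 2-fold rises were chosen before. A single value far from the other 3 of its group was looked for in 20 sets of values (10 measures in each group), where chance gives about 1 for unselected normal values. It was found in 2, both for sham replicate 4. Its log2 intensity for probe ILMN_2712075 was 9.19, on the side of the hepatectomy arrays. Its score on the second principal component was -25.4, outside the range of both groups (4.84 to 8.37 for the other sham arrays and -2.37 to 4.19 for the hepatectomy arrays), so this value is a difference from both.

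On the probes that changed at least 2-fold sham replicate 4 was shifted toward the hepatectomy arrays, and its difference from another sham array correlated across 12811 probes with the hepatectomy change measured against the remaining 2 sham arrays, with r of 0.394, 0.503 and 0.401 for sham replicates 1, 2 and 3 as partner (among these 3 arrays, r was 0.266 for replicate 1 against 2, 0.249 for 3 against 2 and 0.013 for 1 against 3), which argues against random noise of a poor array as the whole source (probes are not independent replicates). Its median position of 0.23 on rising probes, with an upper quartile of 0.38 and no hepatectomy array below 0.85, argues against an exchanged label. Admixture of hepatectomy RNA at a single share stays open: on the linear scale its median shares in rising and falling probes differed by -0.151 (95% interval of resampled probes -0.205 to -0.096), which lies outside the range of sham replicates 1 to 3 (-0.097 to -0.0073) but overlaps the interval of sham replicate 1 (-0.147 to -0.067). Over the 31 probes that rose at least 8-fold in the fit without this array its share ran from 0.0022 to 0.38 (quartiles 0.058 and 0.154), an uneven shift, but these are only the strongest probes and the hepatectomy arrays differ among themselves. A different mix of cells and a stronger response to the operation in this sample also stay open and were not tested, because both need gene names.

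Among probes with a change of at least 2-fold, rises outnumbered falls; no biological explanation was tested for this. Cyclic loess moved the mean of a brightness class on an array by up to 0.053 on the log2 scale. It raised the share of rises among all called probes from 46.3% to 55.5%. Of the 2-fold changes, 76.2% still rose (exact 95% interval 72.5 to 79.6). The trends with brightness that it found were thus small beside a 2-fold change. Shifts this small can move few probes across the 2-fold line, so this share was nearly fixed in advance. The small size of the shifts itself argues against brightness trends left between these arrays as the source of the excess. The probes that rose at least 2-fold had a median log2 change of 1.49. Whether the authors' normalization hid or added such a trend was not tested. Centring each array on its median left 73.5% rising but moved no array by more than 0.0056, so a single scaling factor per array stays open. Hidden falls of probes that start near the intensity floor stay open too: 67.8% of the 2-fold changes rose among the 2563 probes brightest over all arrays (exact 95% interval 60.3 to 74.8), but that choice admits probes that were dim in sham and had no room to fall. Among the 10% of probes brightest in sham 56 rose and 87 fell (39.2% rising, exact 95% interval 31.1 to 47.7), and among the 10% brightest after hepatectomy 196 rose and 30 fell (86.7% rising, 81.6 to 90.9), but a choice on a single group favours probes brighter in that group, so neither decides.

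The separation of the groups was checked against the other ways to split the 8 arrays into 4 and 4. Of the 35 splits, 1 gave at least 4423 probes past the threshold in limma, the real one, and the highest of the others gave 0. This is a share of 0.0286, the smallest that 35 splits can give. The groups had already been seen to separate when this test was chosen. Their difference also adds to the spread within the groups of every other split. The share was thus nearly fixed in advance and excludes nothing by itself. It says nothing about variation between mice beyond these samples.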

How the results depend on the processing

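Each count of changed probes stayed within 1.5 times its reported value under every alternative, except the counts of 2-fold changes after the normexp background correction, added after the data were seen, where 704 probes rose and 338 fell at least 2-fold instead of 429 and 157; removing background enlarges the folds of dim probes by construction. Under the other alternatives that kept all 8 arrays, the number of called probes ranged from 4181 with the replicate number as a block to 5003 with array weights. Without a block it was 4423, and 4025 of the blocked calls were among these, all in the same direction. The numbers gave no sign of pairing the samples, and no sham array correlated best with the hepatectomy array of its own number. With so few arrays chance often gives no such match, so pairing cannot be excluded. Leaving out each array in turn gave 3585 (without sham replicate 3) to 5122 (without sham replicate 4) called probes, 1685 to 2285 that rose, 1875 to 2837 that fell, 389 to 477 that rose at least 2-fold and 152 to 181 that fell at least 2-fold. Between 3497 and 4208 of the calls left by these fits were among the 4423, all in the same direction. The filter to the 12811 probes brighter than the median called 4840. Falls outnumbered rises under every alternative except cyclic loess (2379 rose, 1910 fell), and the cause was not tested. The share of rises among 2-fold changes stayed between 67.6% and 76.2%. The 4 named probes kept their direction and an adjusted p under 0.05 in all 17 alternatives, with log2 changes of 4.89 to 6.16 for ILMN_2712075, 4.58 to 5.53 for ILMN_1246800, -3.52 to -3.18 for ILMN_1215862 and -3.76 to -2.97 for ILMN_2737710. The fall of ILMN_2737710 was the larger of the pair in 4 of these alternatives: without sham replicate 4 (-3.43 against -3.19), without hepatectomy replicate 4 (-3.34 against -3.23), with array weights (-3.29 against -3.21) and after normexp (-3.76 against -3.52). The alternative that averages a gene's probes and the tests of gene lists were not run, because no gene names are used.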

Other observations

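Over the 4423 called probes, a value far from the other 3 of its group was found for 321 probes (7.26%) in sham and for 211 (4.77%) after hepatectomy. Chance gives about 5% for unselected normal values. These probes were chosen by a test that depends on the spread within groups, so neither share can be judged against that rate. Sham replicate 4 was the distant array for 195 of the 321, and for 146 of these it lay on the side of the hepatectomy arrays. Each of the other arrays was the distant one for 28 to 64 probes.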
